A study of Homo sapiens with 18 samples.

How the data were processed

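The series holds 18 tumour libraries of HCT116 PTDSS2-knockout xenografts in 3 groups of 6, vehicle and DS55980254 at 10 and 30 mg/kg. The compound was given by mouth in 0.5% methylcellulose and tumours were taken after 24 hours. Per the labels, total RNA was extracted with a Promega Maxwell kit, and libraries were made from 5 ng of RNA with the Clontech SMARTer Stranded Total RNA-Seq Kit for pico input. The submitters' notes name STAR 2.4.2a and the genome builds hg19 and mm10 without saying what each was used for. How reads were assigned to human or mouse, the annotation version and the quantification tool are not given in the sources used here.

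The authors deposited 1 gene table per library, in the layout of RSEM, with 25343 human genes by Entrez gene ID. Per the file headers, the values are expected counts, which are estimated reads per gene that are not scaled. The deposited tables also give TPM, abundances scaled for transcript length by the authors, which were used in 1 alternative. Gene symbols came from a reference annotation, matched by ID for 25220 genes and by transcript accession for 26, and 97 had no symbol. No coordinates are given, since the annotation behind the counts is unknown. Total counts per library ran from 433981 to 8538792.

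Expected counts were rounded to whole numbers. Genes with too few counts were removed by filterByExpr on the 3 groups, which left 14074 genes. Libraries were scaled by TMM and fitted together with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. Contrasts were each dose against vehicle, the doses against each other, any difference among the groups, and a straight line over the dose steps 0, 1 and 2. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes carry the model's estimate, and levels are normalised counts (CPM, scaled to library size) with the SD over 6 libraries. PTDSS1 and PTDSS2 were also tested alone by two-sided exact permutation of log2(CPM + 0.5) over 924 arrangements.

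Before the data were examined, 27 gene lists were fixed from textbook knowledge. They covered lipid synthesis and transport, cholesterol, stress responses, cell cycle and replication, histones, apoptosis, p53, interferon, NF-kB, hypoxia, immediate early genes, YAP, NRF2, Wnt, lysosome, intestinal differentiation, respiratory chain, ribosomal proteins and mitochondrially encoded genes. Markers of fibroblasts, endothelium, leukocytes, and erythroid, muscle, skin and adipose cells were included because host cells are present in such tumours. The 24 lists with at least 5 members past the filter were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes, were run beside it. A list score is the mean log2 CPM of its members in a library.

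Genes to be named were also chosen by a rule fixed before the data were examined. It takes PTDSS1 and PTDSS2, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM. It adds up to 4 members with the smallest p from each list that passed, and 1 or 2 members of the other lists if they passed alone. Where fewer than 5 genes passed, the 5 with the smallest p are named as not having passed. Small RNA genes stayed out of the largest changes.

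The model was tested on simulated data made from the counts, with 200 genes changed. Comparing 30 mg/kg with vehicle, edgeR recovered 46.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97% of those changed 4-fold. Of its 159 calls, 9 were unchanged genes. For 10 mg/kg against vehicle the shares were 49.3%, 74.6% and 98.5%, and 13 of 161 calls were unchanged genes. In the comparison of the doses the shares were 41.8%, 80.6% and 95.5%. A list of 30 genes shifted 1.25-fold was found in each comparison, and 0 of 20 unchanged lists were called. Other splits of the real libraries gave medians of 5, 5 and 4 lists with the preset correlation, so the simulation understates false calls of lists.

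Agreement of the doses was measured as the correlation and covariance of their fold changes and the overlap of calls, beside 20 simulations of unchanged groups and beside fits in which each dose had its own 3 vehicle libraries. Alternatives were DESeq2 1.42.0 size factors, library totals alone, no filter, at least 5 CPM in 6 libraries, limma-voom, limma-trend on log2(TPM + 1), DESeq2, the groups compared alone, and each library left out. Added after the data were seen were voom with sample weights, slopes of each library on gene length and on GC content as covariates, the hypoxia score as a covariate, and 10 mg/kg replicate 2 and 30 mg/kg replicate 5 left out together. GC content was available for 94.5% of the genes tested. Other splits of the libraries into groups of the same sizes, 100 per comparison with the labelled one included, were fitted in the same way. Tables and exact tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. No library was left out of the main results. Some genes that the naming rule selects, and 2 of 4 gene lists chosen after the data were seen, were tested and are not reported here, while counts and adjusted p-values include them.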

Results

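RNA was sequenced from 18 tumours grown in mice from HCT116, an established human colon cancer line, in which PTDSS2 had been knocked out. PTDSS1 and PTDSS2 encode the enzymes that make phosphatidylserine by exchanging the head group of other phospholipids. The series concerns a PTDSS1 inhibitor and cancer cells that have lost PTDSS2, and the labels name the dosed compound by its code, DS55980254. Mice received vehicle, 10 mg/kg or 30 mg/kg by mouth, with 6 tumour libraries per group collected 24 hours later, so each comparison asks which transcripts differed a day after dosing. Counts assigned to human genes totalled between 3435423 and 8538792 in 17 libraries and 433981 in 10 mg/kg replicate 2, which sets the coarsest precision. That library also correlated least with the others, with a mean correlation of 0.726 of its log2 values against 0.942 to 0.954 for the remaining 17. Silent olfactory receptor genes reached 4.31 CPM (normalised counts) per kb in it, against 0.0338 to 1.11 in the others (median 0.075). The highest of those others was 10 mg/kg replicate 4, which also had the most genes with a count (21578). The labels do not say whether each tumour came from a separate mouse, so the p-values measure the spread between samples.

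PTDSS1 (Entrez gene 9791), the enzyme that the series is about, was transcribed at 76.8 ± 4.94 CPM (SD, n = 6) with vehicle. Its level was 64.7 ± 5.45 CPM at 10 mg/kg and 67.9 ± 4.54 CPM at 30 mg/kg (SD, n = 6 each). Over all genes tested it did not pass at 10 mg/kg (log2 fold change -0.23, adjusted p = 0.379) or at 30 mg/kg (-0.18, adjusted p = 0.62). Tested alone, a two-sided exact permutation test gave p = 0.00649 for 10 mg/kg and p = 0.013 for 30 mg/kg against vehicle, and p = 0.286 between the doses. PTDSS2 (Entrez gene 81490), the gene knocked out by the labels, still had counts at 8.75 ± 2.3 CPM with vehicle, 9.43 ± 2.32 at 10 mg/kg and 7.91 ± 3.36 at 30 mg/kg (SD, n = 6 each). Gene counts cannot show whether these transcripts carry the edit. Exact permutation p-values for PTDSS2 were 0.6 for 10 mg/kg and 0.511 for 30 mg/kg against vehicle, and 0.251 between the doses.

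At 10 mg/kg, genes of cholesterol synthesis and uptake rose together. INSIG1, the endoplasmic reticulum protein that holds back the sterol-regulated transcription factors, rose from 40.0 ± 8.28 to 112 ± 7.68 CPM (SD, n = 6), a 2.80-fold rise. HMGCS1, an early enzyme of the mevalonate pathway, rose 2.34-fold, and MVD, which acts later in it, 2.10-fold. Genes of the ATF4 amino acid stress response and of NF-kB signalling were also higher. Fewer genes were lower, among them DKK1, a secreted Wnt antagonist, and AMOTL2, an angiomotin family member that binds YAP.

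In all, 66 of 14074 genes differed between 10 mg/kg and vehicle, 59 higher and 7 lower, and 1337 genes had an unadjusted p under 0.05, against 704 for evenly spread p-values and up to 1925 in other splits of the libraries. Of the 25 cholesterol genes measured, 17 rose over all genes tested and 24 rose adjusted over the list alone, with a median log2 fold change of 0.71. That list passed with the preset correlation (adjusted p = 1.5e-30) and with an estimated one (adjusted p = 0.00345). Of 27 ATF4 genes, 3 rose over all genes and 13 rose adjusted over the list alone, with a median of 0.37 (adjusted p = 0.00174 with an estimated correlation). CHAC1, which degrades glutathione, rose 2.98-fold, TRIB3, a pseudokinase, 1.65-fold, and CEBPG, a transcription factor of the C/EBP family, 1.40-fold. In 10 mg/kg replicate 2 TRIB3 stood at 64.2 CPM, against at most 38.3 CPM in the rest of its group. CEBPG stood at 92.0 CPM in it, against at most 71.6 CPM, while CHAC1 was lowest of its group there, at 4.28 CPM. SLC7A11, the cystine importer, was at 1.68-fold without passing (adjusted p = 0.0551). Of 15 NF-kB genes, 2 rose over all genes, and adjusted over the list alone 5 rose and 1 fell, with a median of 0.33 (adjusted p = 0.00373 with an estimated correlation). RELB, an NF-kB subunit, rose 1.88-fold and NFKBIA, which encodes the inhibitor of NF-kB, 1.60-fold. Both were highest in 10 mg/kg replicate 2, RELB at 51.3 CPM against 23.6 to 37.9 CPM in the rest of its group. NFKBIA stood at 85.6 CPM in it, against 47.4 to 68.0 CPM.

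Other lists passed at 10 mg/kg with the preset correlation but not with an estimated one. Of these, fry passed for DNA replication and S phase (adjusted p = 0.009) and for immediate early genes (adjusted p = 0.00615). Fatty acid synthesis had a median of 0.27 over 17 genes (adjusted p = 0.146 with an estimated correlation). In it 3 genes rose over all genes, and 7 rose adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, rose 1.87-fold, the stearoyl desaturase gene SCD 1.91-fold and the fatty acid synthase gene FASN 1.48-fold. The score of this list in 10 mg/kg replicate 2 was 5.81, against 6.66 to 6.82 in the rest of its group. With vehicle it was 6.31 to 6.41. SCD stood at 622 CPM in that library and FASN at 1797, against at least 1866 and 2270 in the rest of its group. ACSS2 was not low there. Immediate early genes had a median of 0.24 over 23 genes (adjusted p = 0.0596 with an estimated correlation). Of these, 4 rose over all genes, and adjusted over the list alone 8 rose and 1 fell. The transcription factor gene JUN rose 1.79-fold, EGR3 2.78-fold and KLF6 1.43-fold, and DUSP4, a MAP kinase phosphatase, rose 1.40-fold. In 10 mg/kg replicate 2 EGR3 stood at 49.2 CPM, against 8.79 to 14.8 CPM in the rest of its group. JUN stood at 400 CPM in it, against 199 to 264 CPM, while KLF6 and DUSP4 were not high there. DNA replication and S phase had a median of -0.35 over 27 genes, with 0 past the threshold over all genes and 19 that fell adjusted over the list alone (adjusted p = 0.116 with an estimated correlation). The origin licensing gene CDT1 stood at 0.777-fold (adjusted p = 0.199) and the replicative helicase gene MCM4 at 0.726-fold (adjusted p = 0.203). The medians were -0.29 for 25 genes of G2 and M phase (adjusted p = 0.19 with an estimated correlation) and -0.37 for 14 replication-dependent histones (adjusted p = 0.19 with an estimated correlation). For 51 cytoplasmic ribosomal proteins the median was -0.17 (adjusted p = 0.374 with an estimated correlation). For 6 fibroblast markers it was 0.59 (adjusted p = 0.0290 with the preset and 0.284 with an estimated correlation), and without 10 mg/kg replicate 2 or vehicle replicate 3 the preset test gave 0.369 or 0.0596. None of the last 4 lists had a member past the threshold over all genes. Adjusted over the list alone, 1 histone fell. Scores of 10 mg/kg replicate 2 for G2 and M phase, histones and ribosomal proteins were 5.06, 5.23 and 8.01. The rest of its group stood at or above 6.05, 6.53 and 8.61, so that library lowers the group's values.

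Outside these lists, the largest rises at 10 mg/kg by the naming rule were FGFBP1, which releases fibroblast growth factors from the matrix, at 3.54-fold and LONRF2 at 2.97-fold. In 10 mg/kg replicate 2 LONRF2 stood at 49.2 CPM, against 8.02 to 14.2 CPM in the rest of its group. FGFBP1 stood at 0 CPM in it, against 7.47 to 21.5 CPM. LIPG, the endothelial lipase, rose 2.78-fold, LBH 2.44-fold, the keratin gene KRT6B 2.39-fold, and TSC22D3, the glucocorticoid-induced leucine zipper, 2.30-fold. LPIN1, a phosphatidate phosphatase in the phospholipid list, rose 1.93-fold, and the lysosomal sialidase gene NEU1 1.58-fold. DKK1 fell from 22.8 ± 7.73 to 8.79 ± 2.94 CPM and AMOTL2 from 92.6 ± 9.15 to 50.0 ± 8.51 CPM (SD, n = 6 each), to 0.384 and 0.531 of the vehicle level. The others that fell were SUSD2 (0.631-fold), the DNA helicase gene BLM (0.655-fold), PABIR2 (0.674-fold), the histone gene H2AC13 (0.689-fold) and E2F7, a repressor of cell cycle genes (0.710-fold). The count of 66 became 121 without 10 mg/kg replicate 2, and 42, 40 or 31 without vehicle replicate 1, 2 or 5. It was 468 with DESeq2, 12 with limma-trend on TPM, 32 without a filter, 36 from the groups compared alone, 105 and 104 with gene length and GC slopes as covariates, and 235 with voom sample weights.

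**Figure D1:**
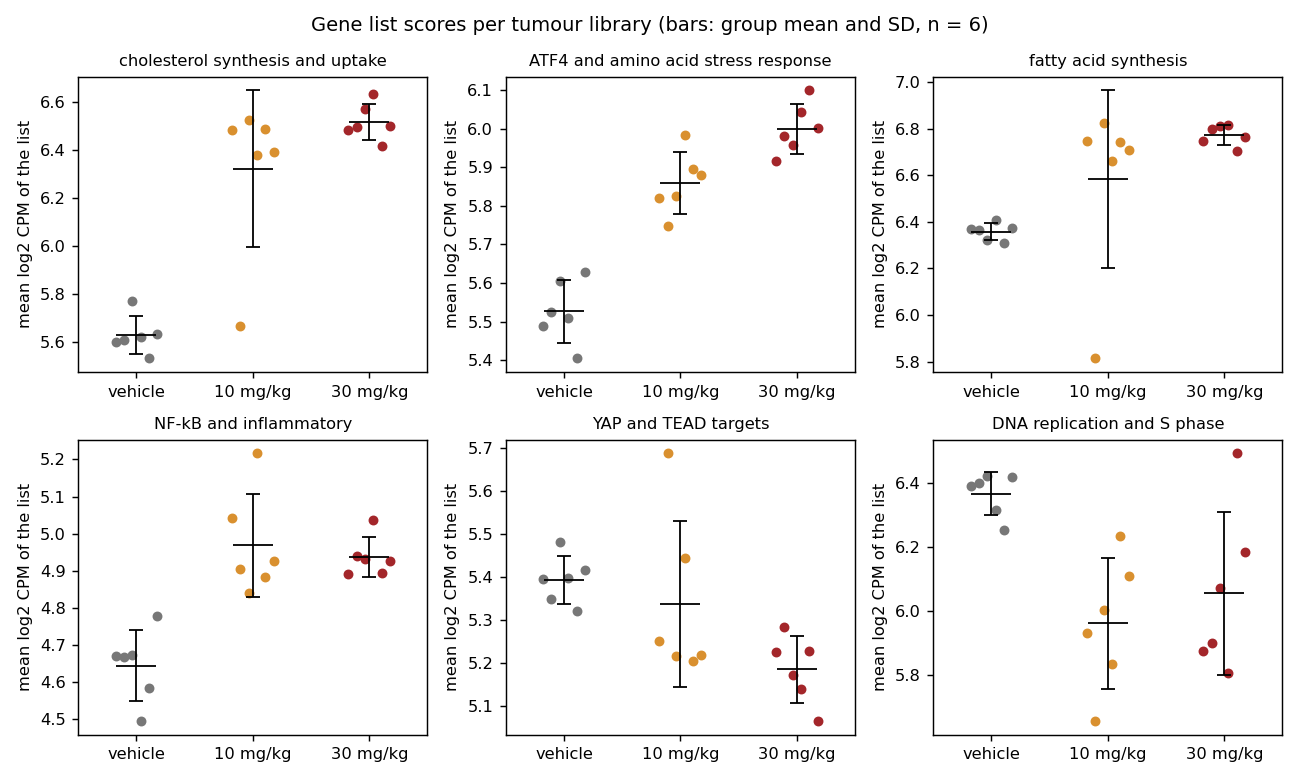
Mean log2 CPM of the members of 6 gene lists, as points for the 18 tumour libraries by dose, with bars for the group mean and SD (n = 6). For cholesterol genes the 30 mg/kg mean was 6.52 against 5.63 with vehicle, and the low 10 mg/kg point at 5.67 is replicate 2.

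At 30 mg/kg, cholesterol genes rose again and more members of the ATF4 response passed. INSIG1 rose 3.03-fold to 121 ± 14.4 CPM and HMGCS1 2.73-fold to 188 ± 18.8 CPM (SD, n = 6 each). CHAC1 rose 3.64-fold, from 2.21 ± 0.609 to 8.17 ± 3.33 CPM, SLC7A11 2.06-fold, and ASNS, which makes asparagine, 1.80-fold. Fatty acid synthesis genes rose as a group and targets of YAP and TEAD, the growth-regulating transcription factors of the Hippo pathway, fell as a group. AMOTL2 fell to 41.2 ± 4.97 CPM (SD, n = 6), 0.446 of the vehicle level.

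In all, 87 of 14074 genes differed between 30 mg/kg and vehicle, 80 higher and 7 lower, with 1112 at an unadjusted p under 0.05, against 704 for evenly spread p-values and up to 1458 in other splits of the libraries. Of 25 cholesterol genes, 20 rose over all genes and 24 rose adjusted over the list alone, with a median log2 fold change of 0.90 (adjusted p = 8.1e-05 with an estimated correlation). MSMO1, which demethylates sterol intermediates, rose 2.59-fold, ACAT2, which joins acetyl-CoA units, 2.36-fold, and MVD 1.91-fold. Of 27 ATF4 genes, 6 rose over all genes and 18 rose adjusted over the list alone, with a median of 0.44 (adjusted p = 5.5e-06 with an estimated correlation). TRIB3 rose 1.71-fold, to 39.9 ± 4.88 from 23.3 ± 3.61 CPM (SD, n = 6 each). Of 17 fatty acid synthesis genes, 3 rose over all genes and 11 rose adjusted over the list alone, with a median of 0.36 (adjusted p = 0.00651 with an estimated correlation). SCD rose 2.27-fold, ACSS2 1.93-fold and FASN 1.52-fold. Of 23 immediate early genes, 3 rose over all genes, and adjusted over the list alone 6 rose and 1 fell, with a median of 0.28 (adjusted p = 0.0169 with an estimated correlation). These were JUN (1.56-fold), KLF6 (1.51-fold) and DUSP4 (log2 fold change 0.58), while MYC stood at 0.759-fold (adjusted p = 0.165).

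Among 15 NF-kB genes at 30 mg/kg, 1 rose over all genes and 4 rose adjusted over the list alone, with a median of 0.30 (adjusted p = 0.00188 with an estimated correlation). It was BIRC3, an inhibitor of apoptosis, at 1.64-fold, while RELB had a log2 fold change of 0.58 (adjusted p = 0.198). Among 18 YAP and TEAD targets the median was -0.21 (adjusted p = 0.00651 with an estimated correlation). Over all genes 2 fell, AMOTL2 and ARHGEF17 (0.664-fold), and 1 rose, NT5E, the ectonucleotidase CD73 (1.76-fold). Adjusted over the list alone, 7 fell and 1 rose. Among 20 apoptosis regulators the median was 0.10 (adjusted p = 0.0378 with an estimated correlation), and PMAIP1, the pro-apoptotic protein NOXA, rose 1.59-fold, the only member past the threshold over all genes or over the list alone.

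Lists that passed camera at 30 mg/kg with the preset correlation alone were DNA replication and S phase, NRF2 targets, phospholipid synthesis, histones and lysosome. Of these, fry also passed for DNA replication (adjusted p = 0.0332), NRF2 targets (0.0496) and phospholipid synthesis (0.0459). DNA replication had a median of -0.30 over 27 genes, with 0 past the threshold over all genes and 2 that fell adjusted over the list alone (adjusted p = 0.0582 with an estimated correlation). FEN1, which processes Okazaki fragments, was at 0.772-fold (adjusted p = 0.159) and CDT1 at 0.779-fold (adjusted p = 0.159). NRF2 targets had a median of 0.22 over 19 genes, with 1 rise over all genes, SLC7A11, which the ATF4 list also holds, and 3 adjusted over the list alone (adjusted p = 0.0586 with an estimated correlation). Genes of phosphatidylserine, phosphatidylethanolamine and phospholipid synthesis had a median of 0.06 over 30 genes (adjusted p = 0.0375 with the preset and 0.0851 with an estimated correlation). The same 2 members rose over all genes and over the list alone, LPIN1 2.00-fold and PCYT2, which makes CDP-ethanolamine for phosphatidylethanolamine, 1.39-fold. This list no longer passed the preset test without vehicle replicate 1, 3 or 6 (adjusted p = 0.107, 0.0513 and 0.0558) or without 30 mg/kg replicate 2 or 4 (0.0648 and 0.0851). Histones had a median of -0.29 and 0 past the threshold over all genes, with 1 fall adjusted over the list alone (adjusted p = 0.295 with an estimated correlation). Lysosome and autophagy genes had a median of 0.11, with 0 past the threshold over all genes and 2 rises adjusted over the list alone (adjusted p = 0.295 with an estimated correlation).

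Other rises at 30 mg/kg were FGFBP1 at 3.22-fold, LIPG at 2.55-fold and KRT6B at 2.38-fold. The genes that fell besides AMOTL2 and ARHGEF17 included PPP2R3B, a regulatory subunit of protein phosphatase 2A (0.565-fold), and SLC1A3, a glutamate and aspartate transporter (0.580-fold). BLM fell to 0.618 of its vehicle level and SHPK, a sedoheptulose kinase, to 0.721. The count of 87 became 182 without 10 mg/kg replicate 2, which shares the estimate of spread. It was 226 with DESeq2, 23 with limma-trend on TPM, 57 without a filter, 191 from the groups compared alone, 170 with the GC slope as a covariate, and 315 with voom sample weights.

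**Figure D2:**
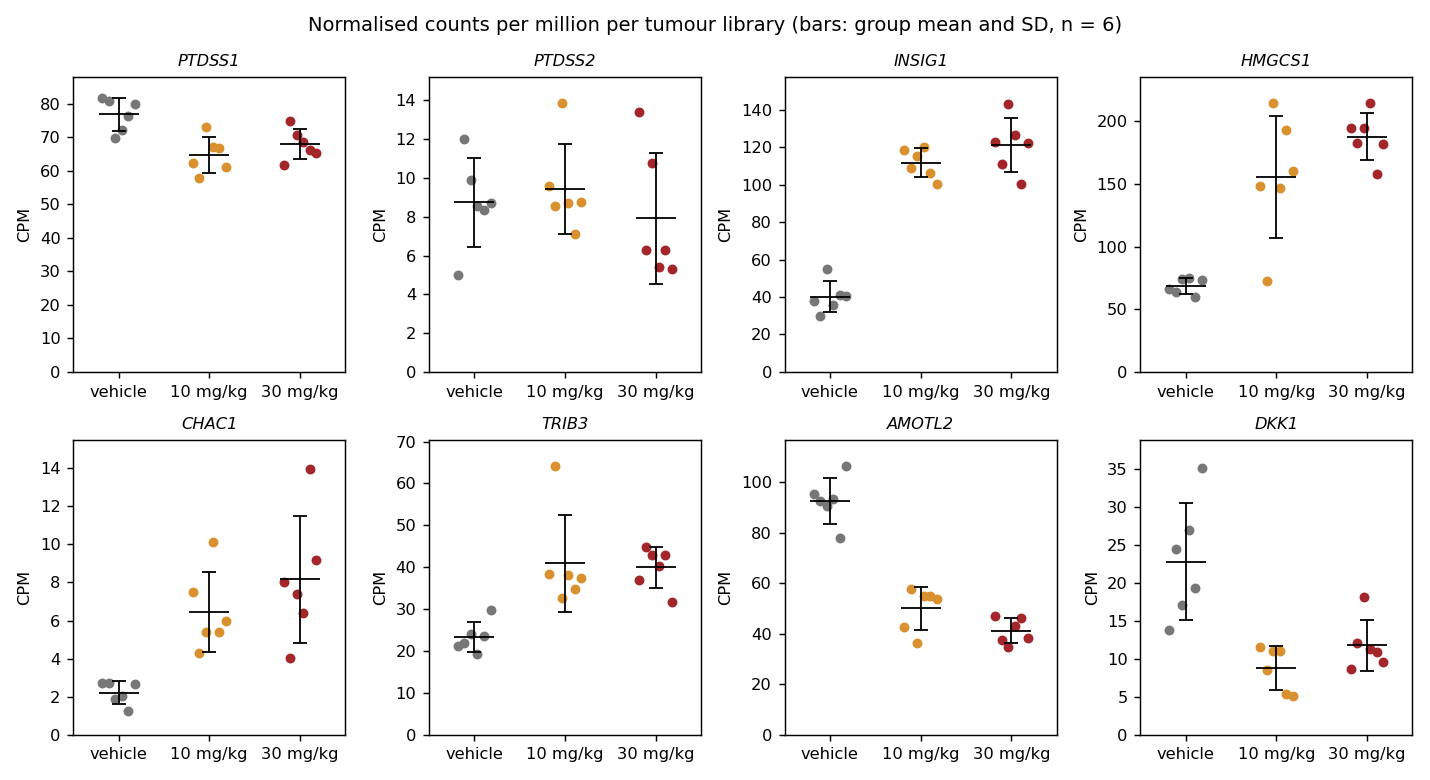
Normalised counts (CPM) of 8 genes, as points for the 18 tumour libraries by dose, with bars for the group mean and SD (n = 6) and axes from 0. INSIG1 stood at 40.0 CPM with vehicle and 112 and 121 CPM at the doses, and AMOTL2 at 92.6, 50.0 and 41.2 CPM.

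Some calls of named genes ended when 1 library was left out. For 10 mg/kg this held for CHAC1 (adjusted p = 0.0505), RELB (0.0505) and FASN (0.0746) without vehicle replicate 5, and for CEBPG without vehicle replicate 1 or 5 (0.0586 and 0.0738). LONRF2 (up to 0.0706), KLF6 (up to 0.0622) and NEU1 (up to 0.0543) each ended without any of 3 vehicle libraries, namely replicates 1, 2 and 5, replicates 1, 4 and 5, and replicates 2, 4 and 5. FGFBP1 ended without any of 4 libraries (up to 0.0904), PABIR2 and NFKBIA without any of 7 (up to 0.107 and 0.118), BLM without any of 8 (up to 0.118) and SCD without any of 9 (up to 0.0969). EGR3 and SUSD2 ended without any of 10 (up to 0.116 and 0.131), E2F7 without any of 11 (up to 0.132) and H2AC13 without any of 12 (up to 0.135). For 30 mg/kg, JUN ended without vehicle replicate 1, 2 or 5 (up to 0.0593), NT5E and PPP2R3B without any of 7 libraries (up to 0.106 and 0.0755), and FGFBP1 without any of 8 (up to 0.0897). BIRC3 ended without any of 10 (up to 0.149) and SHPK without any of 15 (up to 0.172). The remaining named calls held without each library in turn, 15 at 10 mg/kg and 24 at 30 mg/kg, among them INSIG1, HMGCS1, AMOTL2 and LPIN1 at both doses.

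Lists on other processes did not pass at either dose with either correlation. The medians at 10 and 30 mg/kg were -0.06 and -0.01 for p53 targets, -0.05 and -0.03 for the interferon response, and 0.05 and 0.10 for hypoxia and glycolysis. They were 0.02 and 0.06 for endoplasmic reticulum chaperones, -0.05 and 0.08 for the nuclear-encoded respiratory chain, and 0.26 and 0.36 for endothelial markers. Phosphatidylserine flippases and scramblases had medians of -0.02 and 0.03, the latter opposite in sign to the mean of -0.06, and the Wnt and stem cell list 0.16 and 0.01, where the mean at 30 mg/kg was -0.04. Intestinal differentiation, with 5 genes measured, had medians of 0.20 and 0.25. Among these lists DKK1 was the only member past the threshold over all genes at 10 mg/kg, and at 30 mg/kg there was none. Lysosome, NRF2, apoptosis, phospholipid and YAP lists did not pass at 10 mg/kg with either correlation, with medians of 0.10, 0.06, 0.09, 0.08 and -0.16. By fry the YAP list passed there as lower (adjusted p = 0.026). At 30 mg/kg G2 and M phase (-0.09), ribosomal proteins (-0.05) and fibroblast markers (-0.06, where the mean was 0.14) did not pass. Without 10 mg/kg replicate 2 the preset test at 10 mg/kg passed for lysosome (adjusted p = 0.0007), NRF2 (0.0007), YAP (0.00403), endoplasmic reticulum chaperones (0.0152) and Wnt (0.0214). At 30 mg/kg G2 and M phase passed without vehicle replicate 1 (0.0492), 10 mg/kg replicate 2 (0.0108) or 30 mg/kg replicate 5 (0.00136). Hypoxia passed without 10 mg/kg replicate 5 at 10 mg/kg (0.00966) and without 30 mg/kg replicate 5 at 30 mg/kg (0.0068). Without vehicle replicate 3 the preset test passed for Wnt at 10 mg/kg (0.0464) and for chaperones (0.0307) and the respiratory chain (0.0219) at 30 mg/kg. Chaperones also passed at 30 mg/kg without 10 mg/kg replicate 2 (0.0422) or 30 mg/kg replicate 5 (0.0335), and the respiratory chain without 30 mg/kg replicate 1 (0.0167) or 4 (0.014).

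Over the lists together, 10 of 24 passed at 10 mg/kg and 12 at 30 mg/kg with the preset correlation, and 3 and 7 with an estimated one. Leukocyte markers, with 4 past the filter, and erythroid, muscle, skin and adipose markers, with 3, were too few to test. Leukocyte markers summed to 17.5 CPM with vehicle, 18.1 CPM at 30 mg/kg and 21.1 CPM at 10 mg/kg without replicate 2, and to 115 CPM in that replicate. The erythroid and muscle group summed to 51.1, 61.9, 62.8 and 221 CPM in the same order. For mitochondrially encoded genes 0 members were found, so that list was not analysed here.

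Between 30 and 10 mg/kg, 0 of 14074 genes differed by edgeR, and 496 had an unadjusted p under 0.05, against 704 for evenly spread p-values and up to 4179 in other splits of the libraries. DESeq2, voom, voom with sample weights and limma-trend also gave 0. The smallest p-values, none of which passed (adjusted p = 0.969), belonged to Entrez gene 162699 (0.185-fold), CCDC88B (0.632-fold), IL10RA (0.361-fold), ABHD8 (0.640-fold) and FAM107B (1.28-fold). With the preset correlation 6 lists passed, each with a positive median and 0 genes past the threshold, and with an estimated correlation 0 passed. Medians were 0.19 for G2 and M phase, 0.12 for ribosomal proteins and 0.13 for cholesterol (adjusted p = 0.647 each with an estimated correlation). They were 0.12 for the respiratory chain and 0.13 for NRF2 targets (adjusted p = 0.647 each with an estimated correlation) and 0.11 for the ATF4 response (adjusted p = 0.362 with an estimated correlation). The count of 6 became 3 without 10 mg/kg replicate 2 or without 30 mg/kg replicate 5, 11 without 10 mg/kg replicate 5, 30 mg/kg replicate 1 or 30 mg/kg replicate 2, and 10 without 30 mg/kg replicate 4.

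Asking for any difference among the groups gave 80 genes, and a straight line over the dose steps gave 69, of which 62 rose and 7 fell with dose. AMOTL2, BLM, SLC1A3 and ARHGEF17 passed both tests. The first count became 154 without 10 mg/kg replicate 2, and 53 or 47 without vehicle replicate 4 or 5. The second became 136 without 10 mg/kg replicate 2, and 31, 38, 39, 37 or 40 without vehicle replicate 1, 2, 4, 5 or 6.

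The fold changes of the doses correlated more than in simulations of unchanged groups against the same vehicle libraries. Genes were also called higher at both doses when the doses shared no vehicle library. How much of the correlation the common vehicle libraries and variation shared by genes account for is not settled here. Of the 59 genes higher at 10 mg/kg and the 80 at 30 mg/kg, 49 were shared, where 0.335 would be expected for independent lists and 0.05 on average in simulations of unchanged groups against the same vehicle libraries. With no gene changed, such simulations hold few calls that could overlap, so the last value does not test agreement. Of 7 lower at each dose 2 were shared, AMOTL2 and BLM. Over 14074 genes, which are not independent replicates, the correlation of the fold changes was 0.583, against 0.445 to 0.517 in 20 simulations. The simulations drew each gene independently, so their range leaves out variation that genes share across libraries. With separate vehicle libraries, 3 for each dose, the correlation averaged 0.263 and ranged from 0.167 to 0.345, with 10 to 16 genes called higher at both doses. The covariance was 0.0457, against 0.0264 in the simulations. With separate vehicle libraries it was 0.0284, and those fits still hold any effect of dose, so they do not stand for unchanged groups.

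**Figure D3:**
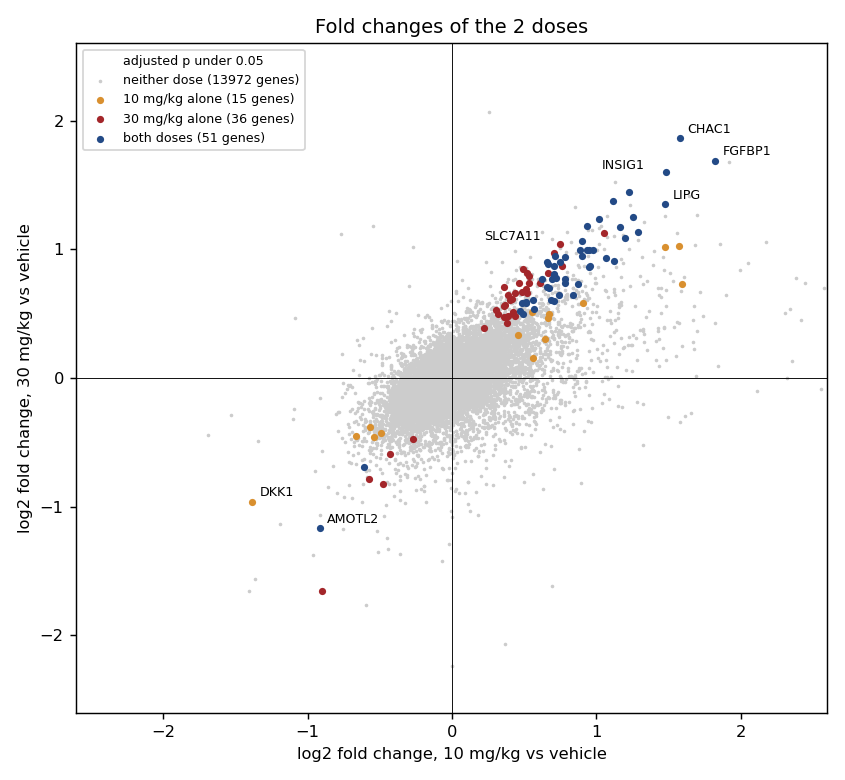
Log2 fold change against vehicle of 14074 genes at 10 mg/kg (horizontal) and 30 mg/kg (vertical), coloured by adjusted p under 0.05 at both doses (51 genes), 10 mg/kg alone (15), 30 mg/kg alone (36) or neither, with 9 genes beyond the axes. Both comparisons share the vehicle libraries, and CHAC1, INSIG1 and FGFBP1 lie among the highest called genes.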

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

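The tests of olfactory receptor genes and host markers that are silent elsewhere, of single host genes, of the covariates on cholesterol and replication genes, and of other splits for list counts with an estimated correlation and for genes at an unadjusted p under 0.05 were chosen after the results were seen. In 105 sets of 6 libraries, 21 held a library far from the others, where 5.25 would be expected by chance, and 12 of the 21 concern 10 mg/kg replicate 2.

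10 mg/kg replicate 2 stood apart in total count (433981), in mean correlation with the other libraries (0.7259) and in its scores, mostly low ones. Low depth alone is argued against, since each other library thinned to the same total kept a mean correlation of at least 0.924, against 0.770 for this library on the same comparison. Transcripts of mouse host cells counted as human cannot be told apart. Host cell markers held 4.76 times the median share of the other libraries, above the 3.18 times of olfactory receptor genes, and PECAM1 (18.4 CPM, at most 4.66 elsewhere), VWF (20.7, at most 8.79) and COL1A1 (290, at most 103) were high, while LYZ (2.3, at most 9.39) and CD74 (2.3, at most 3.37) were not and HBB was at 0. COL1A2, which fibroblasts make together with COL1A1, stood at 2.3 CPM (1 count, at most 1.75 elsewhere) and rose by 0.0112 of the rise of COL1A1, far below what host fibroblasts would bring if both were counted. That test does not decide, since in the other libraries COL1A2 had a median of 0 CPM beside 84.3 for COL1A1. Neither does the share, since host markers silent elsewhere reached 2.52 to 4.33 CPM per kb, not beyond the 4.31 of silent olfactory receptor genes except in 1 of 4 groups. Genomic DNA in the library remains a candidate explanation. Olfactory receptor genes held 2.45 times the share of the next library, short of the 3 times predicted, and some such as OR52D1 are expressed here. Those silent elsewhere stood at 3.88 times the highest other level per kb, that of 10 mg/kg replicate 4. By the same measure silent host markers stood at 4.75 to 7.02 times, so this ratio does not set genomic DNA apart from host transcripts. No biological explanation was tested for this library.

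Cholesterol genes rose at both doses. For 30 mg/kg a trend with gene length between libraries is argued against, since the median was 0.899 with that slope as a covariate, as without it. So is GC content there, at 0.907. These values do not cover 10 mg/kg, where replicate 2 had the highest slopes of all libraries on length (0.0711) and GC content (0.0397). The dose of the compound is the design's biological explanation and remains open as a hypothesis. Measuring sterols would show whether sterol levels changed, and would not by itself test the dose.

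DNA replication genes were lower at both doses by their list medians, a pattern whose call ended with an estimated correlation. The trend with gene length (median at 30 mg/kg -0.334 with the slope as a covariate, -0.296 without) and the oxygen supply of single tumours (-0.322 with the hypoxia score as a covariate) are argued against as its whole cause. So is a chance difference between a few tumours in how many cells cycle, since exact permutation of the score gave p = 0.00216 at 10 mg/kg, with all 6 libraries below all vehicle libraries, and p = 0.026 at 30 mg/kg, with 5 of 6 below. Adjusted over the lists the p-values were 0.013 and 0.052, so the evidence at 30 mg/kg is the weaker. The dose may also lower the share of cycling cells, which was not tested.

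A chance division of the libraries is argued against for the gene counts against vehicle, as far as 100 splits can show. They were 66 at 10 mg/kg against 0 in the highest other split and 87 at 30 mg/kg against 1, and the labelled split alone (1 of 100) reached the count. The same held for any group (80 against 1) and for the trend (69 against 3). For 30 against 10 mg/kg the count of 0 was reached by all 100 splits, the highest at 2004 genes. That split, and another with 558 genes, point to a structure of the samples. The mean slopes on gene length of their sides were -0.0155 and 0.0273, and 0.0189 and -0.00713. Without 10 mg/kg replicate 2, which has the highest slope (0.0711) and lies on the low side of both, they were -0.0328 and 0.0273, and 0.0189 and -0.0228. Whether the slope accounts for these splits was not tested. For genes at an unadjusted p under 0.05 other splits reached the labelled count in every comparison, so chance is not excluded. At 10 mg/kg 3 of 100 splits were as high (1337 against 1925 in the highest other split), few enough to count against chance by the rule applied to the splits. At 30 mg/kg it was 5 of 100 (1112 against 1458), and between doses 51 of 100 (496 against 4179). For lists with the preset correlation chance cannot be excluded, with 10 against 11 in the highest other split at 10 mg/kg (11 of 100 as high), 12 against 17 at 30 mg/kg (8 of 100) and 6 against 11 between doses (36 of 100). With an estimated correlation chance is argued against, within these splits, at 10 mg/kg (3 against 1, reached by 1 of 100) and 30 mg/kg (7 against 4, by 1 of 100). Between doses 0 was reached by all 100.

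The other values far from their group are given without an explanation. The score of 10 mg/kg replicate 2 was low, against the other 5 libraries of its group, for cholesterol (5.665), fatty acid synthesis (5.814), endoplasmic reticulum chaperones (5.978), G2 and M phase (5.058) and lysosome (5.075). It was also low for NRF2 targets (5.272), the respiratory chain (5.494), ribosomal proteins (8.014) and histones (5.232), and its TRIB3 level was high (64.17 CPM). The total count of 30 mg/kg replicate 1 was high (8538792). Scores were high for NF-kB in 30 mg/kg replicate 4 (5.037), for hypoxia in vehicle replicate 3 (7.634), for immediate early genes in vehicle replicate 3 (6.192) and for histones in 30 mg/kg replicate 5 (7.003). In 10 mg/kg replicate 5 the hypoxia score (6.651) and the immediate early score (6.032) were low. PTDSS2 was high in 10 mg/kg replicate 3 (13.88 CPM) and DKK1 in 30 mg/kg replicate 3 (18.18 CPM).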

How the results depend on the processing

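Voom with sample weights, the slopes on gene length and GC content, the hypoxia score and the pair of libraries left out together were alternatives chosen after the data were seen. Numbers of genes against vehicle at 10 mg/kg (66), at 30 mg/kg (87), over any group (80) and for the trend (69) are given in that order where any of them moved by over 1.5 times. They were 32, 57, 47 and 41 with no filter, which tests more genes, 468, 226, 384 and 251 with DESeq2, and 12, 23, 13 and 3 with limma-trend on TPM. They were 235, 315, 263 and 336 with sample weights, and 104, 170, 144 and 133 with the GC slope. Without 10 mg/kg replicate 2 and 30 mg/kg replicate 5 together they were 135, 212, 185 and 183. The gene length slope gave 105 at 10 mg/kg, and the groups compared alone gave 36 at 10 mg/kg and 191 at 30 mg/kg. Replicate numbers do not pair the samples, since same-number pairs across groups had a median correlation of -0.0446 and other pairs 0.00968, and with the numbers as a block the counts were 24, 60, 42 and 33. Leaving out each library gave 31 to 121, 61 to 182, 47 to 154 and 31 to 136, and 0 in each case for the doses against each other. List counts (10, 12 and 6 for the low dose, the high dose and between doses) were 18 at the low dose and 17 between doses with no filter. They were 3, 7 and 0 with an estimated correlation, 6 at the low dose and 0 between doses with fry, 2 between doses with the length slope and 0 without the 2 libraries. Leaving out each library gave 10 to 14, 11 to 15 and 3 to 11. Host cell lists that passed went from 1 at 10 mg/kg to 0 without 10 mg/kg replicate 2. The correlation of the doses (0.583) was 0.263 with separate vehicle libraries, 0.621 with the strict filter and 0.663 without 10 mg/kg replicate 2. Of 61 calls of named genes, 19 held under every alternative run and 42 ended under at least 1. No called value changed sign, and 56 values that were never called did. With lists, 62 calls ended and 82 appeared over the alternatives. Except for the number of genes or samples tested, the cause was not tested. At this depth and spread the simulations recovered 46.3% of genes changed 1.5-fold at 30 mg/kg.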

Other observations

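The lists of synthetases were chosen after the fold changes were seen, as were the tests without 10 mg/kg replicate 2. At 30 mg/kg the genes of cytoplasmic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median log2 fold change of 0.16, and 17 of 20 were above 0. GARS1 rose 1.52-fold, AARS1 1.43-fold and MARS1 1.40-fold, while the list passed with the preset correlation alone (adjusted p = 0.0847 with an estimated correlation, over 4 such lists). Without 10 mg/kg replicate 2, which shares the estimate of spread, it also passed with an estimated one (adjusted p = 0.035). At 10 mg/kg the median was 0.0561 (adjusted p = 0.456 with the preset correlation), and without replicate 2 it was 0.0554 (adjusted p = 0.00234 with the preset and 0.143 with an estimated correlation). At 30 mg/kg the 17 mitochondrial synthetases had a median of -0.135 (adjusted p = 0.0423 with the preset and 0.0847 with an estimated correlation). Since the lists were picked for fold changes seen in these libraries, their p-values do not test the rise independently. AARS1 and other synthetases are also members of the ATF4 list, so the 2 lists are not independent.

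Pooled over the groups, tumours with a higher hypoxia score than their group mean tended to have a lower DNA replication score. The groups were not tested one by one, and vehicle replicate 3 had the highest vehicle score of both lists (7.63 and 6.42). Over 18 libraries, with both scores centred on their group means, Pearson's r was -0.721 (permutation p = 0.0008) and Spearman's rho -0.511 (permutation p = 0.0316). Without the 2 libraries farthest from the median, 10 mg/kg replicate 5 and 30 mg/kg replicate 5, r was -0.369 (permutation p = 0.16). Without 10 mg/kg replicate 2, r was -0.812 (permutation p = 0.00022), and without it and those 2 libraries -0.55 (permutation p = 0.0339), where Spearman's rho was -0.404 (permutation p = 0.138). The strength of the relation thus depends on which libraries are kept. No other pair of scores was tested in this way.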
